A study of Homo sapiens with 136 samples.

How the data were processed

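The starting values were gene counts deposited by the authors for each library. The table holds whole numbers that are not normalised. The submitters list kallisto 0.44.0 and GRCh38; the role of each, the transcript annotation and the step from transcripts to genes are not given in the sources used here. The table held 25435 gene symbols, of which 4605 had no count in any library. Gene positions were taken from GENCODE v29 on GRCh38, in which 24008 of the symbols were found. Raw reads were not used here.

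Titles gave each library's line and plate. Each line was grown in multi-well plates of its own, A and B, with 34 libraries each. Each treatment was split equally over both, so plate entered every fit. The baseline difference between the lines cannot be told apart from plate and was not tested. Libraries on the same plate deviated from their group means together only in part. Over 435 pairs of treatments, the median correlation of these deviations was 0.0559 in AsPC-1 (range −0.1428 to 0.2576) and 0.0756 in PANC-1 (range −0.2503 to 0.3552). It was over 0.1 in 30.6% and 40.5% of pairs. The plate term itself passed for 1604 and 2082 genes, and without this replicate block the class-by-inhibitor count for MEK inhibitors in AsPC-1 was 7 in place of 12. Correlation of log2 counts between replicates of a group was at least 0.889, no libraries were duplicates of each other, and none was left out.

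Each line was fitted once over its 68 libraries with edgeR 4.0.16 (quasi-likelihood, robust, TMM factors, filterByExpr by treatment group, 37 residual degrees of freedom). This left 12761 genes in AsPC-1 and 12627 in PANC-1. A class effect is the mean of its drug groups minus the mean of the alone groups, with each autophagy inhibitor weighted equally. The class therefore stands for these drugs and not for a sample of drugs. Tests are two-sided, and p values were adjusted by Benjamini and Hochberg within each comparison, with 0.05 as the threshold for calling a gene. Differences between the lines came from a fit of both lines with plate within line (13960 genes). DESeq2 1.42.0 was run on the same counts as an alternative. The design, the gene lists, the rule for naming genes and all but 3 alternatives were written before the data were examined. The line difference between the autophagy inhibitors and the difference of ERK output scores between them were not in that design.

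The lists cover ERK targets, immediate early genes, receptor tyrosine kinases and adaptive partners, lysosome, autophagy, lipid synthesis, ATF4 targets, protein folding, G1/S, G2/M, ribosome biogenesis under MYC, glycolysis and hypoxia, p53 targets, interferon response, NRF2 targets, epithelial and mesenchymal genes. They also cover genes of mitochondrial DNA and markers of fibroblasts, immune cells and endothelium, cell types not expected in these cultures. Of 666 list genes 657 were in the file. Lists with at least 3 measured members were tested with camera of limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and adjustment over the lists. For single drugs, scores used a prior count of 2, and fry tested the ERK targets and, after the data were seen, the ATF4 targets. Shares of counts per library were compared by permutation within plates, exact where groups held 6 libraries and otherwise with 100000 draws, adjusted over 56 tests.

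Genes were named by a fixed rule. For the comparisons of the autophagy inhibitors and of each class against alone, it takes the ERK targets (classes only) and up to 3 members of every other list with the smallest adjusted p under 0.05. It adds the 5 largest rises and 5 largest falls among called genes with a mean log2 CPM of at least 5. In every other comparison it takes up to 3 called genes per direction with the smallest adjusted p. Genes outside this rule are said to have been chosen after their values were seen; this holds for ATF4, TXNIP and KRT80, for the choice of genes shared between lines, and for all values of single drugs. Some genes that the rule names are not reported here.

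In a simulation with known changes in the same layout, the comparison of autophagy inhibitors recovered 24 of 67 changes of 2-fold in AsPC-1 and 39 in PANC-1, and that of MEK inhibitors 47 and 63. Of the simulated calls for MEK inhibitors, 13.3% in AsPC-1 and 9.47% in PANC-1 were false, most of them falls. Both shares lie above what the threshold for calling a gene is meant to allow. They rest on 22 false calls among 12161 genes simulated without a change in AsPC-1, and 18 among 12027 in PANC-1. Such a share depends on how many changed genes are simulated, so it is not the error rate of the reported calls. R 4.3.3, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 were used.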

Results

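Expression was measured in AsPC-1 and PANC-1, human cell lines from pancreatic ductal adenocarcinoma, by PLATE-Seq, which prepares barcoded RNA sequencing libraries from cells lysed in culture plates. Cells grew for 24 h and were then treated for 24 h with an autophagy inhibitor, either hydroxychloroquine, which raises lysosomal pH and blocks the breakdown of autophagic cargo, or an inhibitor of Vps34, the lipid kinase that starts the autophagosome. Each autophagy inhibitor was given alone (6 libraries per line) or with 1 of 14 inhibitors of the RAF, MEK and ERK kinases (2 libraries per combination), which makes 68 libraries in 30 treatment groups per line. The RAF inhibitors were sorafenib, dabrafenib, RAF709, PLX8394 and GDC-0879. The MEK inhibitors were trametinib, cobimetinib, binimetinib, selumetinib and refametinib. The ERK inhibitors were SCH772984, ulixertinib, AZD0364 and ravoxertinib. Library totals ran from 1419228 to 5871860 counts, with a median of 3351744.5 in AsPC-1 and 3636445.5 in PANC-1. No untreated cells and no kinase inhibitor without an autophagy inhibitor were measured, so each comparison below has an autophagy inhibitor on both sides. Values are log2 fold changes ± standard error and CPM ± SD, where CPM is a gene's count scaled to a common library total. The 2 libraries of a combination lay on different plates, A and B. Whether replicates were independent cultures, and whether alone libraries on the same plate came from separately treated wells, is not stated. The p values therefore measure the spread between these samples, which may be technical.

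The first comparison asks how the autophagy inhibitors differ when given alone. In AsPC-1, 410 genes were higher and 347 lower with the Vps34 inhibitor than with hydroxychloroquine (6 against 6 libraries, 12761 genes tested). The count rests on both plates: within plate A 91 genes passed and within plate B 21, in fits that take the drugs of a class as replicates. Antioxidant genes under the transcription factor NRF2 rose together: 13 of 26 measured members were higher and none lower (15 higher when adjusted over the list alone; camera, adjusted p = 1.62e-16). Among them AKR1C2, a steroid and carbonyl reductase (chromosome 10, 4987400 to 5018031), rose by 0.95 ± 0.08 from 640.8 ± 67.9 to 1176 ± 169 CPM, and PIR, an iron-binding coregulator, by 2.54 ± 0.29 from 3.43 ± 0.73 to 18.9 ± 6.08 CPM. AKR1C3 rose by 1.16 ± 0.10, but AKR1C2 and AKR1C3 are close paralogs, so reads can be assigned to the wrong member. Immediate early genes fell, 10 of 33 lower and none higher (15 lower over the list alone, adjusted p = 4.06e-12). EGR1, a growth factor-induced zinc finger protein, fell from 30.4 ± 6.52 to 5.85 ± 2.75 CPM, and FOSL1, an AP-1 subunit (chromosome 11, 65892049 to 65900573), fell by 0.76 on the log2 scale (SE 0.12). Of 31 genes of cholesterol and fatty acid synthesis, 6 were lower and none higher (10 lower over the list alone, adjusted p = 1.25e-06), including MSMO1, a sterol demethylation enzyme (−0.54 ± 0.11), and FADS2 (−1.42 ± 0.29).

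Smaller shifts in AsPC-1 followed the same comparison. Genes of protein folding in the endoplasmic reticulum were higher (3 of 26, 7 over the list alone, adjusted p = 0.00172), among them the chaperone HSPA5 (0.64 ± 0.12). G1/S genes of DNA replication were higher (3 of 45 both genome-wide and over the list alone, adjusted p = 7.05e-04), with the DNA clamp PCNA at 0.49 ± 0.10. Epithelial genes moved both ways with a median of −0.28 (2 higher, 7 lower of 25; 3 higher and 9 lower over the list alone; adjusted p = 0.00172), including keratin 18 (KRT18, −0.38 ± 0.07) and E-cadherin (CDH1, −0.94 ± 0.18). Genes of ribosome biogenesis under MYC had a median of −0.22 with 1 higher and 2 lower of 54, also over the list alone (adjusted p = 8.36e-04), DKC1 at −0.67 ± 0.12. Transcriptional targets of ERK signalling were lower, 3 of 9 genome-wide and over the list alone (adjusted p = 0.00227), and so were receptor tyrosine kinases and their adaptive partners, 2 of 18 (5 over the list alone, adjusted p = 0.0186). Each of these list calls held with an estimated correlation. That for the 13 genes encoded by mitochondrial DNA (5 higher, 6 over the list alone, adjusted p = 1.15e-04) did not: adjusted p = 0.09 with an estimated correlation. The share of counts from mitochondrial messenger RNA was 28.7% ± 0.80 (SD, n = 6) with the Vps34 inhibitor against 25.2% ± 1.45 with hydroxychloroquine (exact permutation within plates, adjusted p = 0.02). The 10 largest genes held 30.1% ± 0.90 against 28.2% ± 1.43 of counts (same permutation test, adjusted p = 0.0347). Among genes with a mean log2 CPM of at least 5, 9 of the 10 largest fold changes came from 1 alone library each, and all 9 lost their call without it: IFI6 went from 5.28 to −0.09 ± 0.37 without Vps34 inhibitor replicate 1, and THAP5 from −4.61 to −1.90 ± 0.77 without hydroxychloroquine replicate 3.

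In PANC-1, the Vps34 inhibitor raised 165 genes and lowered 149 relative to hydroxychloroquine (12627 genes tested). Targets of ATF4, the transcription factor of the integrated stress response, rose: 19 of 38 were higher and none lower (26 higher and 1 lower over the list alone, adjusted p = 2.14e-33). Asparagine synthetase (ASNS, chromosome 7, 97852118 to 97872542) rose by 1.73 ± 0.14 from 34.6 ± 7.85 to 115 ± 15.7 CPM. With it rose the glutathione-degrading enzyme CHAC1 by 1.52 ± 0.15 and the serine synthesis enzyme PSAT1 by 0.93 ± 0.10. ATF4 itself, chosen after its value was seen, rose by 0.83 ± 0.09 from 135 ± 6.64 to 243 ± 20.8 CPM. Lipid synthesis genes fell, 18 of 30 lower and none higher (22 lower over the list alone, adjusted p = 8.4e-32): MSMO1 (chromosome 4, 165327623 to 165343160) went from 356 ± 43.2 to 190.4 ± 13.9 CPM. The thiolase ACAT2 changed by −1.09 ± 0.13 and the sterol sensor INSIG1 by −1.27 ± 0.15. NRF2 genes were higher, 5 of 22 with 1 lower (12 and 1 over the list alone, adjusted p = 6.15e-08), including heme oxygenase 1 (HMOX1, 1.69 ± 0.22) and NQO1 (0.45 ± 0.08). G1/S genes were lower (7 of 45, 13 over the list alone, adjusted p = 8.1e-11), PCNA at −0.54 ± 0.10, and so were epithelial genes (2 of 15, 3 over the list alone, adjusted p = 0.00184), KRT18 at −0.29 ± 0.07. G2/M genes had a median of −0.14 with no member past the genome-wide threshold of edgeR (9 lower over the list alone, adjusted p = 1.55e-06), and ribosome biogenesis genes a median of −0.07 with none past either threshold (adjusted p = 0.0172). These calls held with an estimated correlation, while that for lysosomal genes (1 of 49 higher, 5 over the list alone, adjusted p = 0.0172) did not: adjusted p = 0.3 with an estimated correlation. The count rests on both plates: within plate A 6 genes passed and within plate B 3, in fits that take the drugs of a class as replicates. It was 140 in a fit of the 12 alone libraries and 205 without Vps34 inhibitor replicate 3, against 314. Among genes with a mean log2 CPM of at least 5, 9 of the largest fold changes came from 1 alone library each and lost their call without it, SLC26A4 going from 8.47 to −0.92 ± 0.83 without Vps34 inhibitor replicate 2.

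Both lines shared 19 genes higher and 17 genes lower with the Vps34 inhibitor, against 5.18 and 3.75 expected by chance (one-sided Fisher's exact test, p = 9.82e-07 and 1.95e-07). The expected numbers take every gene as equally easy to call. In opposite directions 16 genes passed, for which no expected number was computed. The shared genes named here were chosen after their values were seen. ASNS, PSAT1 and NQO1 were higher in both lines, but ATF4 targets as a list did not pass in AsPC-1 (2 higher, 4 lower of 36; 2 and 6 over the list alone; median −0.12, adjusted p = 0.402). The lipid genes MSMO1 and INSIG1 were lower in both. ATF4 (−0.05 ± 0.12, adjusted p = 0.906) and CHAC1 (−0.26 ± 0.47, adjusted p = 0.844) did not pass in AsPC-1. TXNIP, a glucose-regulated inhibitor of thioredoxin, fell from 221 ± 41.8 to 52.3 ± 21.2 CPM in AsPC-1 and from 23.8 ± 9.45 to 3.45 ± 1.64 CPM in PANC-1. Keratin 80 (KRT80) changed by −2.30 ± 0.23 and −1.83 ± 0.26. The difference between the autophagy inhibitors itself differed between the lines for 351 of 13960 genes. Among these, TMEM158, a membrane protein, was lower in AsPC-1 (−1.36 ± 0.31) and higher in PANC-1 (1.26 ± 0.14), a difference of 2.62 ± 0.30. PCNA was higher with the Vps34 inhibitor in AsPC-1 and lower in PANC-1, with a difference of −1.03 ± 0.14. RNR1, the 12S ribosomal RNA of mitochondria, was at 20575 ± 5084 CPM with hydroxychloroquine and 4889 ± 469 with the Vps34 inhibitor in AsPC-1, and at 5906 ± 378 and 4367 ± 563 in PANC-1, a difference between the lines of 1.53 ± 0.13.

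**Figure D1:**
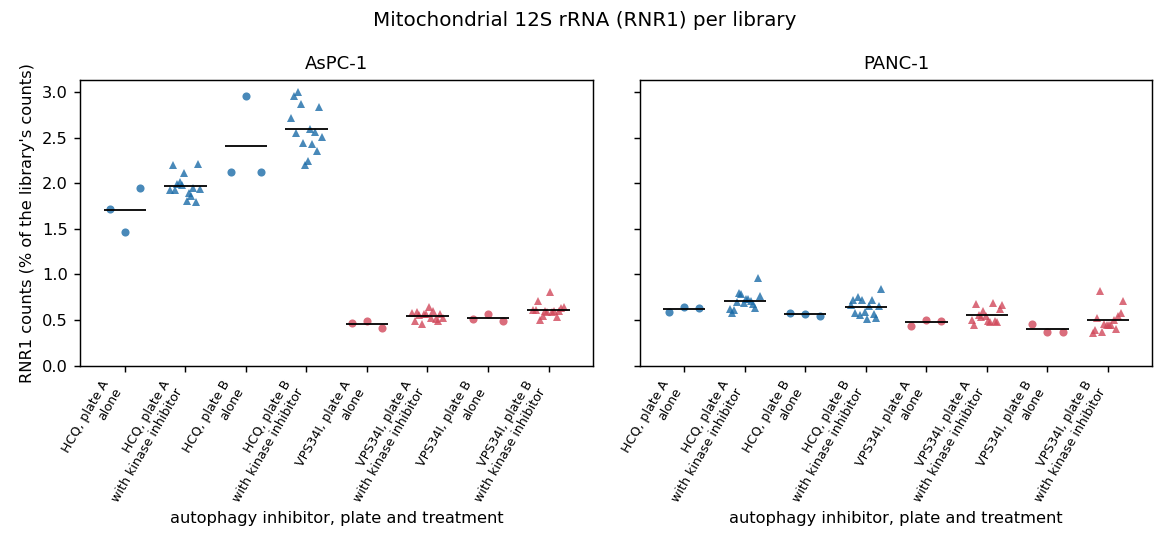
Share of counts (percent, vertical axis) from the mitochondrial 12S ribosomal RNA in each library, by autophagy inhibitor, cell line and presence of a kinase inhibitor; points are libraries and bars are means. In AsPC-1 the alone libraries averaged 2.06% with hydroxychloroquine and 0.489% with the Vps34 inhibitor.

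The next comparisons ask what inhibition of each kinase adds to an autophagy inhibitor. In AsPC-1, MEK inhibitors (20 against 12 libraries) raised 1642 genes and lowered 2050. The balance turned with drugs treated as replicates (1814 higher, 1709 lower). In such fits it also turned within plate A (1240 and 1012) and within plate B (826 and 716). All 9 measured ERK targets fell (adjusted p = 1.41e-13). SPRY4, a feedback inhibitor of receptor signalling (chromosome 5, 142310427 to 142326455), fell from 121 ± 41.6 to 17.1 ± 9.04 CPM (−2.84 ± 0.11, below every alone library in 20 of 20). DUSP6, the phosphatase of ERK itself (chromosome 12, 89347232 to 89353271), fell from 71.6 ± 13.8 to 18.5 ± 8.07 CPM. PHLDA1 changed by −1.49 ± 0.07, DUSP4 by −1.54 ± 0.07 and ETV5 by −1.30 ± 0.20. ETV4 changed by −1.27 ± 0.29, EPHA2 by −0.91 ± 0.12, cyclin D1 (CCND1) by −0.70 ± 0.11 and SPRY2 by −0.61 ± 0.22. Of 33 immediate early genes, 22 fell and 2 rose (26 and 2 over the list alone, adjusted p = 7.09e-10). FOSL1 fell from 367 ± 116 to 56.8 ± 27.1 CPM (−2.71 ± 0.08). FOSL2, an AP-1 subunit, was among those that rose (1.37 ± 0.12). Proliferation genes fell: 32 of 45 G1/S genes (36 over the list alone, adjusted p = 4.75e-12), 27 of 51 G2/M genes (30, adjusted p = 1.59e-08) and 43 of 54 genes of ribosome biogenesis (44 lower and 1 higher over the list alone, adjusted p = 4.82e-16), with none higher genome-wide in any of these. Examples are ribonucleotide reductase RRM2 (−0.95 ± 0.09), cyclin B1 (CCNB1, −0.45 ± 0.06) and the nucleolar protein NOP56 (−0.76 ± 0.06).

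Epithelial genes rose in the same AsPC-1 comparison, 18 of 25 with 1 lower (19 and 1 over the list alone, adjusted p = 3.15e-18). AGR2, a secretory-pathway disulfide isomerase (chromosome 7, 16791811 to 16833433), rose by 2.95 ± 0.14 from 9.94 ± 3.3 to 79.3 ± 31.5 CPM, the transcription factor ELF3 by 1.81 ± 0.07 and claudin 3 (CLDN3) by 2.20 ± 0.12. Mesenchymal genes were split, 4 higher and 7 lower of 21 (4 and 8 over the list alone, adjusted p = 0.0111): vimentin (VIM) fell from 3047 ± 225 to 1087 ± 150 CPM, and the transcription factor SNAI2 changed by −1.88 ± 0.10. NRF2 genes rose, 17 of 26 with 2 lower (17 and 3 over the list alone, adjusted p = 8.48e-11), AKR1C2 reaching 3560 ± 617 CPM against 908 ± 305 and ferritin heavy chain (FTH1) rising by 0.85 ± 0.05. Lipid synthesis genes rose, 17 of 31 with 1 lower (19 and 1, adjusted p = 1.49e-07), MSMO1 by 0.83 ± 0.07 and the desaturase SCD by 0.73 ± 0.08. Interferon-response genes rose, 27 of 43 with 1 lower (28 and 1, adjusted p = 3.23e-11), including the nuclease ISG20 (1.19 ± 0.12) and the immunoproteasome subunit PSMB9 (1.27 ± 0.13). Lysosomal genes rose on balance, 18 of 49 with 2 lower (19 and 2, adjusted p = 1.86e-04), with cathepsin D (CTSD) up by 1.21 ± 0.13 and cathepsin L (CTSL) at −1.22 ± 0.09. Of 4 fibroblast markers, LUM rose (1.27 ± 0.10; 1 higher over the list alone, adjusted p = 0.0109). Within single autophagy inhibitors, 2274 genes passed with hydroxychloroquine and 2298 with the Vps34 inhibitor. List calls held with an estimated correlation except for mitochondrial genes (7 of 13 higher in both counts, adjusted p = 0.00534; adjusted p = 0.236 with an estimated correlation). Libraries with MEK inhibitors also had a higher share of counts in their 10 largest genes (32.2% ± 2.59, n = 20, against 29.2% ± 1.52, n = 12; permutation adjusted p = 5.6e-04). They held more mitochondrial messenger RNA (29.2% ± 3.33 against 27.0% ± 2.14, adjusted p = 0.00907) and less ribosomal protein mRNA (10.9% ± 0.71 against 11.7% ± 0.60, adjusted p = 0.00308).

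ERK inhibitors in AsPC-1 (16 against 12 libraries) raised 1749 genes and lowered 2222. This balance turned with drugs treated as replicates (1938 and 1875). In such fits it also turned within plate A (1410 and 1273) and within plate B (947 and 842). Of the 9 ERK targets 8 fell (9 over the list alone, adjusted p = 3.16e-14), with SPRY4 at −3.39 ± 0.12, DUSP6 at −2.92 ± 0.15, ETV5 at −2.27 ± 0.23, DUSP4 at −1.88 ± 0.08, PHLDA1 at −1.81 ± 0.07, ETV4 at −1.61 ± 0.33, EPHA2 at −1.10 ± 0.13 and CCND1 at −1.08 ± 0.12; SPRY2 did not pass (−0.54 ± 0.23, adjusted p = 0.0611). Immediate early genes fell in 20 of 33 cases and rose in 2 (22 and 2 over the list alone, adjusted p = 1.16e-08), FOSL1 at −3.17 ± 0.09. G1/S genes fell in 35 of 45 cases (39 over the list alone, adjusted p = 9.69e-19), G2/M genes in 36 of 51 (39, adjusted p = 7.25e-12) and ribosome biogenesis genes in 44 of 54 (49, adjusted p = 9.69e-19). None of these was higher. RRM2 changed by −1.42 ± 0.09, the helicase subunit MCM7 by −1.05 ± 0.09 and CDK1 by −0.78 ± 0.07. Epithelial genes rose in 19 of 25 cases (21 over the list alone, 1 lower in both, adjusted p = 1.28e-18), AGR2 by 3.20 ± 0.14. NRF2 genes rose in 19 of 26 cases with 3 lower in both counts (adjusted p = 3.36e-14), AKR1C2 by 2.40 ± 0.06. Lipid synthesis genes rose in 20 of 31 cases (21 over the list alone, 1 lower in both, adjusted p = 4.15e-08), SCD by 1.21 ± 0.08. Interferon genes rose in 25 of 43 cases (26 over the list alone, 2 lower in both, adjusted p = 2.81e-10), the MHC light chain B2M by 0.65 ± 0.07, and lysosomal genes in 20 of 49 with 2 lower in both counts (adjusted p = 4.85e-06). The share of ribosomal protein mRNA was 10.9% ± 0.82 (n = 16) against 11.7% ± 0.60 (permutation adjusted p = 0.02), and the 10 largest genes held 31.7% ± 3.18 against 29.2% ± 1.52 (adjusted p = 0.02). The call for mitochondrial genes (4 of 13 higher, 6 over the list alone, adjusted p = 0.02) was lost, adjusted p = 0.294 with an estimated correlation.

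RAF inhibitors in AsPC-1 (20 against 12 libraries) raised 478 genes and lowered 627. This balance turned with drugs treated as replicates (485 and 283). In such fits it also turned within plate A (85 and 39) and within plate B (11 and 2). ERK targets fell in 4 of 9 cases (5 over the list alone, adjusted p = 2.03e-08), with PHLDA1 at −0.63 ± 0.07, SPRY4 at −0.84 ± 0.10, DUSP4 at −0.48 ± 0.07 and DUSP6 at −0.74 ± 0.13; FOSL1 changed by −1.12 ± 0.08. ATF4 targets rose in 7 of 36 cases with 1 lower (8 and 1 over the list alone, adjusted p = 1.38e-05), ASNS by 0.95 ± 0.09 and PSAT1 by 0.62 ± 0.11. Among single drugs this list passed as higher with dabrafenib and PLX8394, whose values are given below. With RAF709, GDC-0879 and sorafenib it did not pass (fry, adjusted over 56 combinations). Their mean log2 CPM of the list changed by −0.13 (sorafenib, Vps34 inhibitor) to 0.12 (GDC-0879, hydroxychloroquine). NRF2 genes rose in 11 of 26 cases with 2 lower (13 and 2, adjusted p = 1.24e-11), AKR1C2 by 0.93 ± 0.05, and epithelial genes in 11 of 25 with none lower (13 over the list alone, adjusted p = 4.1e-13), AGR2 by 1.38 ± 0.14. VIM fell from 3047 ± 225 to 2054 ± 878 CPM. G1/S genes fell in 9 of 45 cases (14 over the list alone, adjusted p = 1.12e-08), G2/M genes in 6 of 51 (12, adjusted p = 8.15e-04) and ribosome biogenesis genes in 17 of 54 (20, adjusted p = 3.9e-11). Mesenchymal genes were lower on balance, 2 higher and 4 lower of 21 (2 and 5 over the list alone, adjusted p = 0.00475), and immediate early genes had 1 higher and 8 lower of 33 (3 and 10 over the list alone, adjusted p = 5.6e-04). The calls for lysosomal genes (8 higher, 1 lower of 49; 11 and 1 over the list alone; adjusted p = 0.00451) and interferon genes (9 higher, 1 lower of 43; 11 and 2 over the list alone; adjusted p = 0.00348) were lost, adjusted p = 0.0694 and adjusted p = 0.0858 with an estimated correlation. The class count depended on its members: 612 genes passed without GDC-0879 and 557 without RAF709. Without GDC-0879, 5 G1/S genes and 2 G2/M genes were lower, and without RAF709 1 G2/M gene.

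In PANC-1, MEK inhibitors raised 998 genes and lowered 1334. All 8 measured ERK targets fell (adjusted p = 1.11e-21): DUSP6 from 17.8 ± 3.37 to 1.76 ± 1.09 CPM (−3.47 ± 0.23), SPRY4 from 43.5 ± 10.1 to 4.85 ± 2.21 CPM (−3.27 ± 0.13), and PHLDA1 (−1.58 ± 0.06), CCND1 (−1.15 ± 0.11), EPHA2 (−1.10 ± 0.16), ETV4 (−2.21 ± 0.39), ETV5 (−2.01 ± 0.13) and SPRY2 (−1.87 ± 0.25) with them. Immediate early genes fell in 22 of 30 cases and rose in 2 in both counts (adjusted p = 5.5e-19), FOSL1 by −1.24 ± 0.06. G1/S genes fell in 31 of 45 cases (36 over the list alone, adjusted p = 5.77e-18), the replication helicase subunit MCM3 by −0.68 ± 0.06, and ribosome biogenesis genes in 11 of 54 with 1 higher (15 and 1, adjusted p = 3.01e-04). Lipid synthesis genes rose in 14 of 30 cases with none lower (20 and 1 over the list alone, adjusted p = 8.58e-11), SCD by 0.77 ± 0.07 and TM7SF2 by 0.75 ± 0.07. ATF4 targets rose in 16 of 38 cases with 1 lower (20 and 3, adjusted p = 8.28e-08), including the stress protein NUPR1 (1.33 ± 0.13) and the amino acid transporter SLC7A5 (0.91 ± 0.10), while the cytokine GDF15 fell (−2.14 ± 0.14). Without trametinib 8 were higher and 2 lower, with a median of 0.03. Interferon genes rose in 9 of 32 cases (10 over the list alone, adjusted p = 0.00429), IFIT1 by 1.04 ± 0.20, and fibroblast markers in 2 of 3 in both counts (adjusted p = 0.0255), COL1A1 by 0.59 ± 0.08. The call for NRF2 genes (12 higher, 2 lower of 22 in both counts; adjusted p = 0.00318) was lost, adjusted p = 0.0551 with an estimated correlation. Among genes with a mean log2 CPM of at least 5, the largest rises were in ID2 (1.51 ± 0.16), a repressor of differentiation factors, SMIM14 (1.41 ± 0.07), the microtubule protein MAP2 (1.38 ± 0.07) and the cytokine CSF1 (1.28 ± 0.08). The 5 largest falls among them lost their call without 1 alone library each, SLC26A4 going from −5.34 to −0.65 ± 0.53 without Vps34 inhibitor replicate 2.

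ERK inhibitors in PANC-1 raised 688 genes and lowered 1096. All 8 ERK targets fell (adjusted p = 4.52e-24), with DUSP6 at −3.79 ± 0.26, SPRY4 at −3.29 ± 0.14, ETV4 at −2.87 ± 0.45, SPRY2 at −1.66 ± 0.26, ETV5 at −1.60 ± 0.13, PHLDA1 at −1.47 ± 0.06, CCND1 at −1.16 ± 0.11 and EPHA2 at −1.11 ± 0.16. Immediate early genes fell in 20 of 30 cases and rose in 1 (21 and 1 over the list alone, adjusted p = 8.7e-18). G1/S genes fell in 31 of 45 (32, adjusted p = 9.77e-20), and in 17 with 1 higher without ulixertinib (median −0.29). G2/M genes fell in 24 of 51 cases with 1 higher (32 and 1, adjusted p = 2.85e-11), including HJURP, which deposits centromeric histone (−0.74 ± 0.08). Without ulixertinib 2 of them were lower and 5 higher, with a median of 0.05. ATF4 targets rose in 19 of 38 cases with 1 lower (23 and 1, adjusted p = 3.63e-16), PSAT1 by 0.78 ± 0.06 and CHAC1 by 0.93 ± 0.10, and in 12 without ulixertinib. Lipid synthesis genes rose in 21 of 30 cases (26 over the list alone, adjusted p = 3.43e-15), SCD by 0.91 ± 0.07, and in 13 without SCH772984. Protein folding genes were higher in 3 of 26 cases with 1 lower in both counts (adjusted p = 0.0257), HSPA5 by 0.55 ± 0.06. NRF2 genes were higher in 8 of 22 cases with 1 lower (9 and 2, adjusted p = 5.02e-04), HMOX1 by 1.09 ± 0.14, and interferon genes in 4 of 32 with 1 lower (5 and 1, adjusted p = 0.0257). The call for lysosomal genes (10 higher, 3 lower of 49; 12 and 3 over the list alone; adjusted p = 3.02e-04) was lost, adjusted p = 0.0626 with an estimated correlation.

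RAF inhibitors in PANC-1 raised 13 genes and lowered 55, and without RAF709 5 genes passed, all lower. SPRY4 (−1.09 ± 0.12), PHLDA1 (−0.41 ± 0.06) and DUSP6 (−0.91 ± 0.20) were the ERK targets that fell, 3 of 8 (4 over the list alone, adjusted p = 2.75e-11). Immediate early genes fell in 2 of 30 cases (12 over the list alone, adjusted p = 1.09e-08), among them LIF, a cytokine of the interleukin 6 family (−0.59 ± 0.10). ATF4 targets had a median of 0.11 with 1 higher and 1 lower of 38 (2 and 1 over the list alone, adjusted p = 4.83e-05), the serine synthesis enzyme PHGDH at 0.38 ± 0.07, and G1/S genes a median of −0.10 with 1 lower of 45 in both counts (adjusted p = 0.0228). Without RAF709 no member of the ERK target, ATF4 target or G1/S lists passed with edgeR, and the medians were −0.11, 0.04 (mean −0.00206) and −0.04. VIM fell from 2704 ± 509 to 2233 ± 572 CPM, while MAP2 rose from 29.6 ± 3.61 to 45.3 ± 20.6 CPM. The count of 68 genes came to 156 with DESeq2 and to 17 with drugs treated as replicates. Also with drugs as replicates, edgeR gave 0 genes on plate A alone (940 at an unadjusted p under 0.05) and 1 on plate B.

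**Figure D2:**
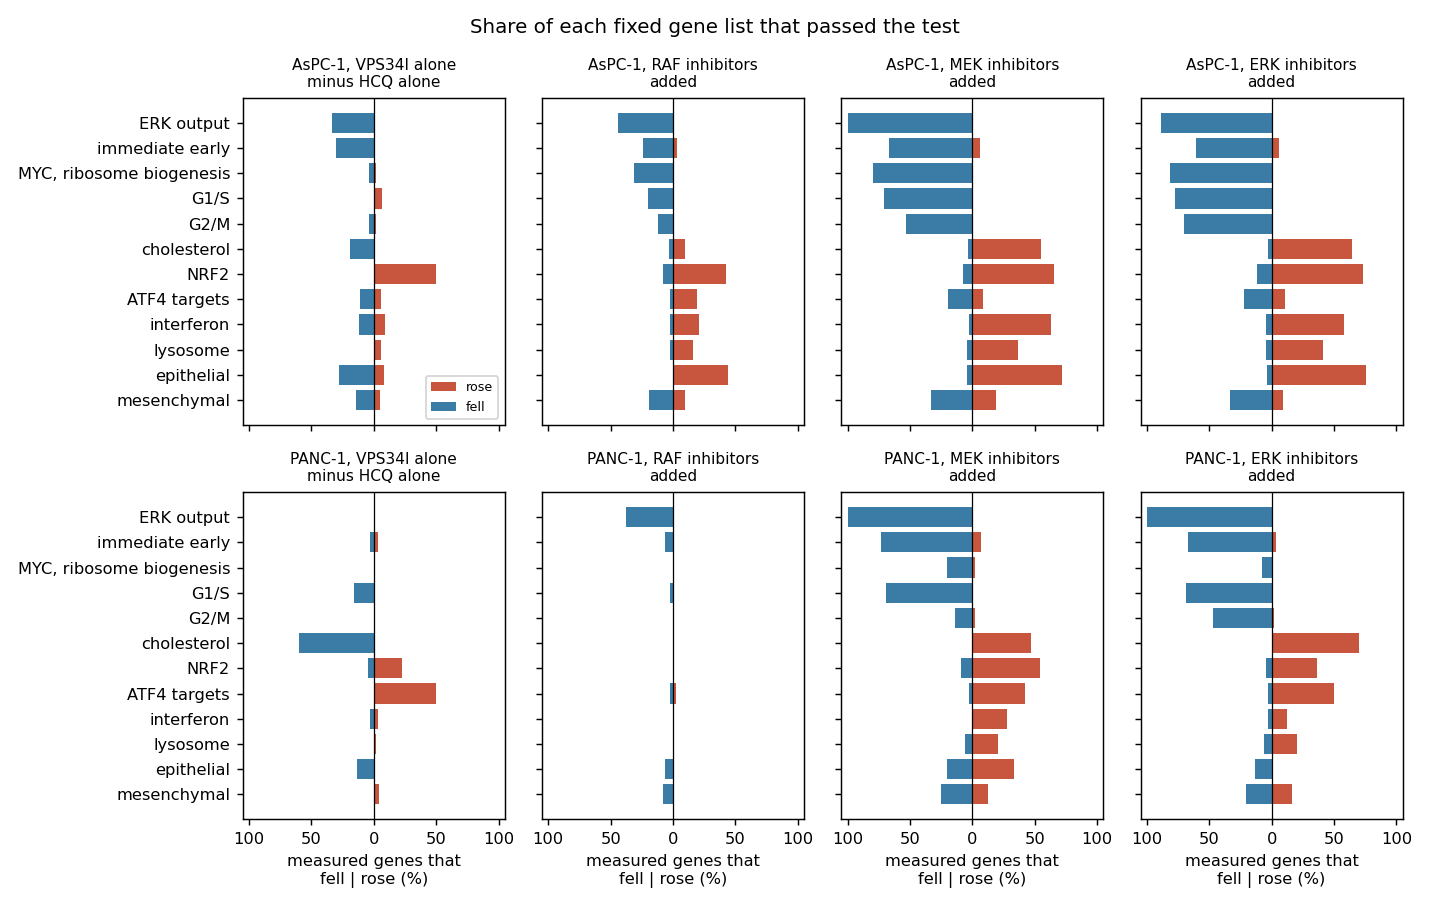
Percent of the measured members of selected gene lists that were higher (right) or lower (left), by line. The comparisons are the Vps34 inhibitor against hydroxychloroquine, both alone, and each kinase inhibitor class against autophagy inhibitor alone. All 8 or 9 measured ERK targets were lower with MEK inhibitors, and 3 of 8 with RAF inhibitors in PANC-1. With MEK inhibitors 18 of 25 epithelial genes were higher and 1 lower in AsPC-1. In PANC-1 5 of 15 were higher and 3 lower, and the list did not pass. The difference of this list between the lines was not tested.

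To rank single drugs, an ERK output score was taken as the mean log2 CPM of the ERK targets minus that of the libraries with the same autophagy inhibitor alone. It was lower for 44 of the 56 combinations of drug, autophagy inhibitor and line and higher for 2 (fry, adjusted over the 56). All 36 combinations with MEK and ERK inhibitors were lower, from −0.75 ± 0.19 (SD, n = 2) for selumetinib with the Vps34 inhibitor in AsPC-1 to −2.33 ± 0.29 for refametinib with hydroxychloroquine in PANC-1. Among RAF inhibitors, RAF709 had the lowest scores, −1.15 ± 0.07 with hydroxychloroquine and −1.12 ± 0.06 with the Vps34 inhibitor in AsPC-1 and −2.05 ± 0.29 and −1.91 ± 0.02 in PANC-1. GDC-0879 (−0.68 ± 0.02 and −0.70 ± 0.21) and dabrafenib (−0.23 ± 0.06 and −0.28 ± 0.04) were lower in AsPC-1, and neither passed in PANC-1. The scores that were higher were in AsPC-1, sorafenib with the Vps34 inhibitor (0.27 ± 0.29, adjusted p = 0.012) and PLX8394 with hydroxychloroquine (0.09 ± 0.16, adjusted p = 0.04). The call for PLX8394 was lost without the plate term (fry, adjusted p = 0.146), and 1 of its 2 libraries scored −0.02. The autophagy inhibitor changed the score in 1 of 28 combinations of drug and line: SCH772984 in AsPC-1 scored −2.24 ± 0.04 with the Vps34 inhibitor and −1.07 ± 0.02 with hydroxychloroquine, a difference of −1.17 (adjusted p = 4.78e-05).

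**Figure D3:**
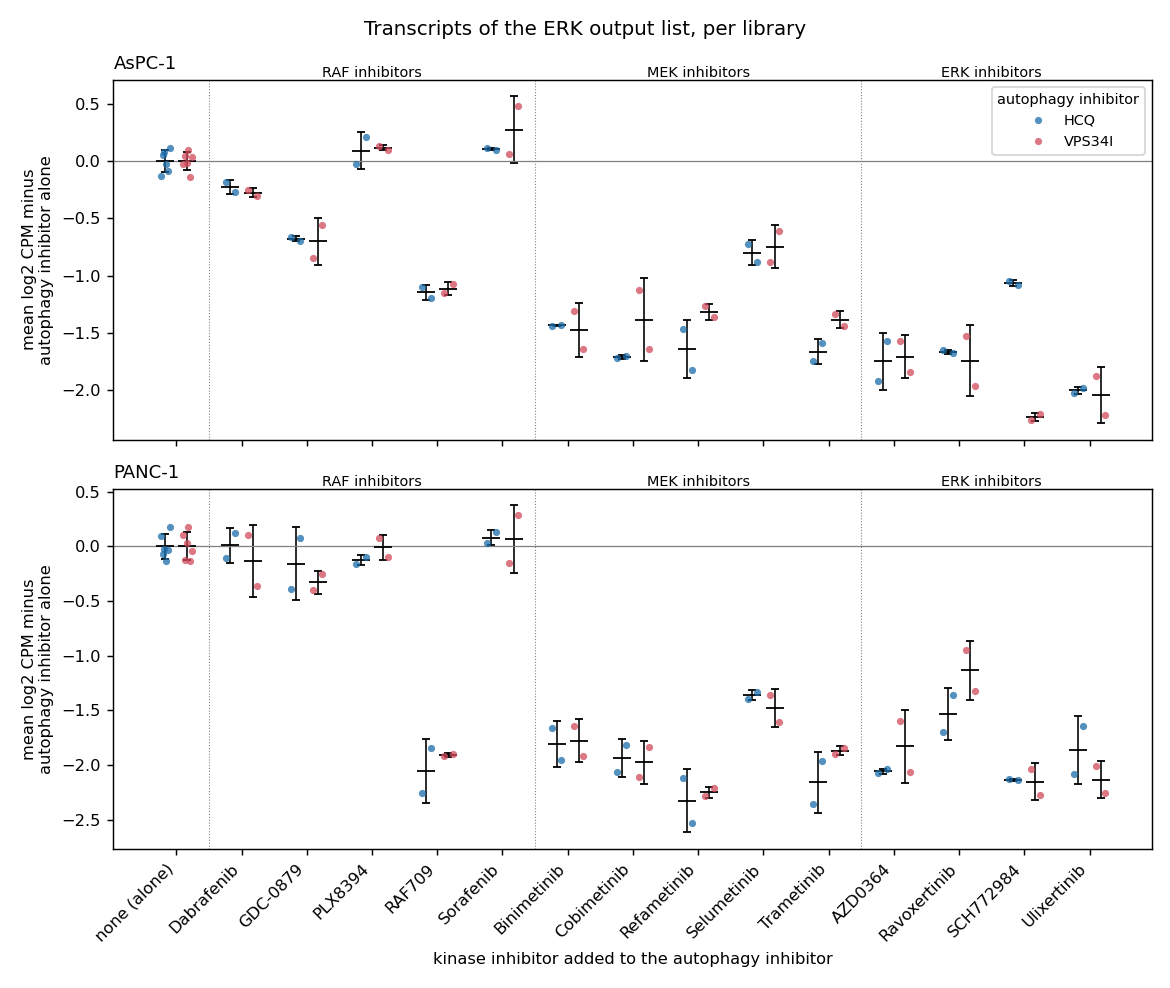
ERK output score (mean log2 CPM of ERK targets minus that with the autophagy inhibitor alone, vertical axis) for each drug, line and autophagy inhibitor. Points are libraries, 2 per drug and 6 for each autophagy inhibitor alone. Ticks are means and error bars SD. MEK and ERK inhibitors all lie below 0, and among RAF inhibitors RAF709 lies lowest, at −2.05 with hydroxychloroquine in PANC-1.

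Drugs of a class also differed from each other. In PANC-1, 143 genes differed among MEK inhibitors, led by CHAC1, PSAT1 and ATF4, and 827 among ERK inhibitors, led by the cell cycle genes RRM2, SPC25 and NEK2. The score of ATF4 targets was 1.23 ± 0.03 for trametinib and 1.02 ± 0.01 for ulixertinib with hydroxychloroquine, and 0.75 ± 0.08 and 0.68 ± 0.12 with the Vps34 inhibitor (SD, n = 2), where no other drug exceeded 0.31 and 0.44 respectively. The following single-drug values were chosen after they were seen. With hydroxychloroquine, CHAC1 rose by 2.43 ± 0.19 with trametinib and 2.53 ± 0.19 with ulixertinib, ASNS by 2.08 ± 0.17 and 1.97 ± 0.17, and ATF4 by 1.33 ± 0.12 and 1.22 ± 0.12. Ulixertinib changed RRM2 by −1.48 ± 0.15 with hydroxychloroquine and −2.05 ± 0.16 with the Vps34 inhibitor, CDK1 by −0.71 ± 0.16 and −1.95 ± 0.18, and CCNB1 by −0.77 ± 0.13 and −1.65 ± 0.14. In AsPC-1, 80 genes differed among MEK inhibitors, 128 among ERK inhibitors and 1356 among RAF inhibitors, the last led by AKR1C2, FERMT1 and VIM. There the highest ATF4 target scores belonged to the RAF inhibitors dabrafenib (0.37 ± 0.06 with hydroxychloroquine, 0.66 ± 0.01 with the Vps34 inhibitor) and PLX8394 (0.40 ± 0.19 and 0.65 ± 0.18). ASNS rose by 1.51 ± 0.18 and 2.41 ± 0.17 with dabrafenib and by 1.29 ± 0.18 and 2.66 ± 0.17 with PLX8394. In PANC-1, 661 genes differed among RAF inhibitors, including SPRY4.

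**Figure D4:**
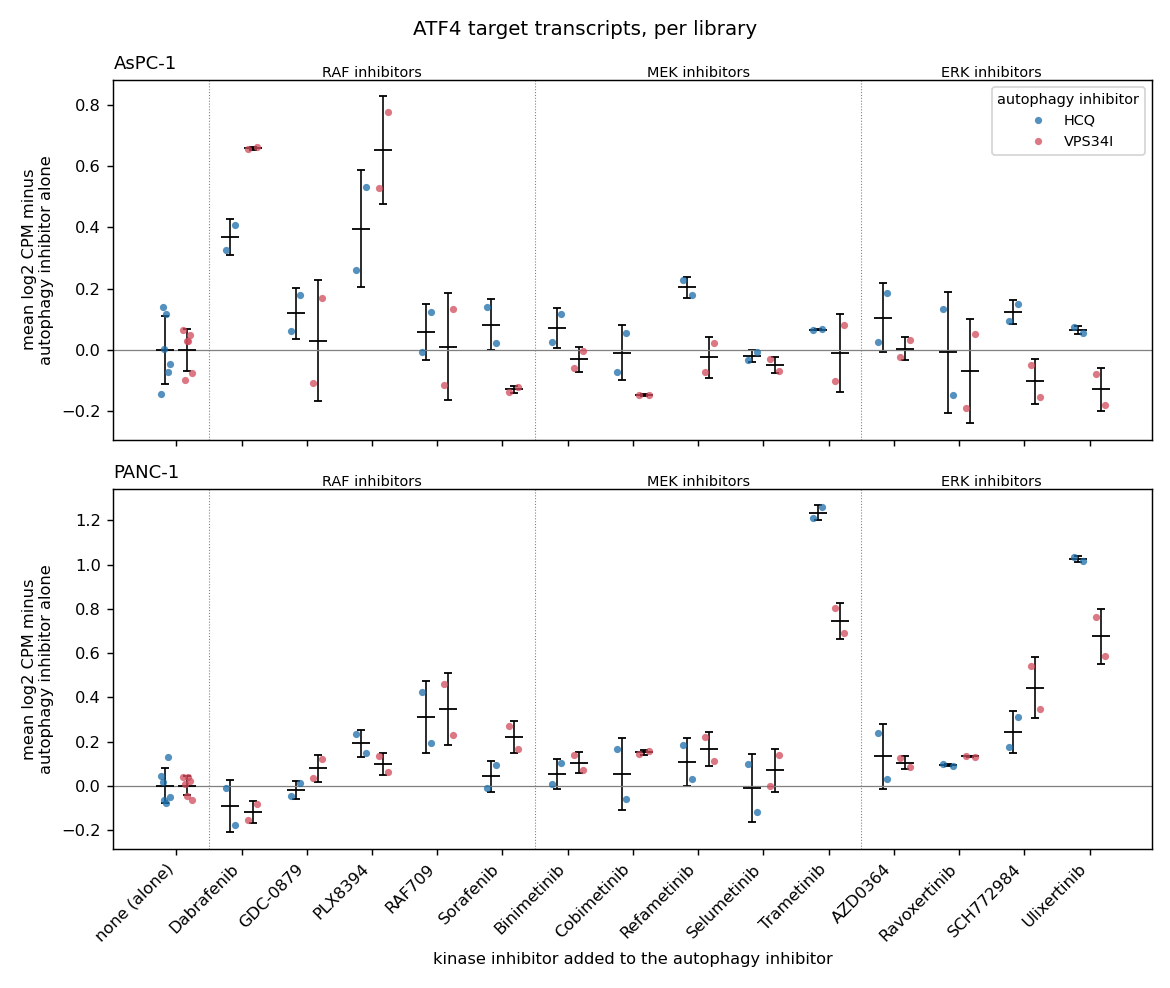
Score of ATF4 target genes (mean log2 CPM minus that with the autophagy inhibitor alone, vertical axis) for each drug, line and autophagy inhibitor. Points are libraries, 2 per drug and 6 for each autophagy inhibitor alone. Ticks are means and error bars SD. Trametinib (1.23) and ulixertinib (1.02) stand apart in PANC-1, and dabrafenib and PLX8394 in AsPC-1.

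Classes were then set against each other within a line. In AsPC-1, 1010 genes were higher and 955 lower with MEK than with RAF inhibitors, AKR1C2 by 1.12 ± 0.04 and FOSL1 by −1.59 ± 0.07, and 1250 were higher and 1285 lower with ERK than with RAF inhibitors. MEK and ERK inhibitors differed in 63 genes higher and 32 lower, 95 in all, against 168 with DESeq2 and 32 (13 higher, 19 lower) with drugs treated as replicates. Of the 95, DUSP6 (0.92 ± 0.15), MCM7 (0.56 ± 0.08) and PCNA (0.35 ± 0.06) were higher with MEK inhibitors, and AKR1C2 (−0.35 ± 0.05) and SCD (−0.47 ± 0.07) higher with ERK inhibitors. In PANC-1, 852 genes were higher and 887 lower with MEK than with RAF inhibitors, SMIM14 by 1.11 ± 0.06 and the surface protein TM4SF1 by −1.06 ± 0.04, and 779 were higher and 891 lower with ERK than with RAF inhibitors, the eIF4E kinase MKNK2 by 0.73 ± 0.05. MEK minus ERK gave 164 higher, among them SSBP3 (0.70 ± 0.07), and 121 lower, 285 in all and 134 with drugs treated as replicates. Doses were set by viability for each drug and are not given in the sources used here, so these contrasts compare doses as well as targets.

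Whether a class acts differently with hydroxychloroquine and with the Vps34 inhibitor was tested as an interaction. In AsPC-1 it passed for 12 genes with MEK inhibitors and 40 with ERK inhibitors. Other splits of the libraries, given below, do not exclude chance for either count. KRT18 rose more with the Vps34 inhibitor, by 0.58 ± 0.08 for MEK and 0.69 ± 0.09 for ERK inhibitors, and AKR1C2 rose less, by −0.76 ± 0.10 and −0.74 ± 0.11. EGR1 differed by 2.35 ± 0.43 for MEK inhibitors, and the mitotic genes NUSAP1 (−1.04 ± 0.16) and CCNB1 (−0.71 ± 0.12) for ERK inhibitors. KRT18, AKR1C2 and EGR1 differed in the opposite direction between the autophagy inhibitors given alone. Their interactions therefore include a change of that starting difference and need not mean a different action of the class. DESeq2 gave 40 and 113 genes, and edgeR without the plate term 7 and 23. With RAF inhibitors in AsPC-1, 0 genes passed with edgeR (725 at an unadjusted p under 0.05, 5 with DESeq2). In PANC-1 edgeR gave 0 genes for each class, with 778, 769 and 688 at an unadjusted p under 0.05 for MEK, ERK and RAF inhibitors; DESeq2 gave 4 for ERK inhibitors.

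Binimetinib and selumetinib share a benzimidazole hydroxamate scaffold and differ by 1 halogen on the anilino ring, fluorine in binimetinib and chlorine in selumetinib. Their doses are not given in the sources used here and need not match. In AsPC-1, 33 genes were higher and 25 lower with binimetinib (4 against 4 libraries), 58 in all, against 139 with DESeq2, 19 without the plate term and 28 to 30 with a replicate of every combination left out (11 higher, 19 lower without replicate 1). Of 9 ERK targets, 3 were lower with binimetinib (6 over the list alone): SPRY2 by −2.06 ± 0.45 (95% interval −2.97 to −1.15, adjusted p = 0.0166), SPRY4 by −1.14 ± 0.23 (−1.61 to −0.68, adjusted p = 0.00738) and DUSP4 by −0.56 ± 0.14 (−0.85 to −0.28, adjusted p = 0.0491). FOSL1 (−0.80 ± 0.16) and the secreted peptide VGF (−1.15 ± 0.21) were also lower, and TRIM31 (0.91 ± 0.14) and FTH1 (0.47 ± 0.09) higher. In PANC-1 edgeR gave 0 genes (662 at an unadjusted p under 0.05, 4 with DESeq2), and 9 to 11 with a replicate of every combination left out. There PHLDA1 differed by −0.50 (interval −0.73 to −0.26, adjusted p = 0.331) and SPRY4 by −0.65 (−1.22 to −0.08, adjusted p = 0.929). Of genes with a mean log2 CPM of at least 5, the interval of the difference lay within 1 log2 unit on either side of 0 for 90.3% of 3472 in AsPC-1 and 93.1% of 4001 in PANC-1.

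Lastly, the lines were compared. MEK inhibitors raised 386 genes and lowered 596 in both lines (106.6 and 200.9 expected by chance among 11526 genes tested in both), and 113 passed in opposite directions. ERK inhibitors raised 280 and lowered 525 (79.2 and 177 expected, 97 opposite). RAF inhibitors gave 5 and 27 (0.438 and 2.61 expected, 5 opposite). No expected number was computed for the opposite directions. Shared with MEK inhibitors were lower SPRY4, DUSP6, PHLDA1 and FOSL1 and higher SCD, the rise being 0.73 in AsPC-1 and 0.77 in PANC-1. The effect itself differed between the lines for 1587 genes with MEK, 1941 with ERK and 235 with RAF inhibitors (13960 genes tested). For RAF inhibitors the count was 153 without the plate term, and chance was not excluded for it. KRT18 (chromosome 12, 52948871 to 52952901) rose with MEK inhibitors in AsPC-1, from 1533 ± 276 to 2509 ± 245 CPM, and fell in PANC-1, from 495 ± 54.3 to 268 ± 44.9 CPM, a difference of −1.67 ± 0.06. SPNS2, a sphingosine-1-phosphate transporter, went the same way (2.35 ± 0.13 in AsPC-1, −2.01 ± 0.12 in PANC-1), and AGR2 rose in AsPC-1 and fell in PANC-1 (−0.32 ± 0.06). VIM fell in both lines, by −1.46 ± 0.04 in AsPC-1 and −0.44 ± 0.04 in PANC-1, a difference of 1.02 ± 0.06. The FOSL1 change in PANC-1 minus that in AsPC-1 was 2.25 ± 0.11 with ERK inhibitors and 0.90 ± 0.10 with RAF inhibitors; with the latter FOSL1 in PANC-1 (−0.22 ± 0.06) did not pass with edgeR (adjusted p = 0.0762) and passed with DESeq2 (adjusted p = 0.0297).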

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

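Most tests of this part were chosen before the result was seen. Those chosen after are the line difference between autophagy inhibitors, the score difference of single drugs, and all tests of an explanation below except that for poor libraries and the regroupings of samples. Interaction tests found 1587 genes whose response to MEK inhibitors differed between the lines, 1941 for ERK inhibitors, 235 for RAF inhibitors and 351 for the difference between autophagy inhibitors. For MEK inhibitors, PANC-1 minus AsPC-1, the genes with the smallest p were DCBLD2 at 1.79, DRAP1 at 1.06, VIM at 1.02, KRT18 at −1.67, SPNS2 at −4.36 and AGR2 at −3.26. Within AsPC-1, the same kind of test found 12 genes for MEK and 40 for ERK inhibitors that responded differently with the Vps34 inhibitor and with hydroxychloroquine. The ERK output score of SCH772984 in AsPC-1 differed between the autophagy inhibitors by −1.17. In 36 checks of groups of 6 alone libraries for a library far from the others, none was found, where chance would give about 1 in 20.

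ATF4 targets in PANC-1 were higher with trametinib and ulixertinib than with other drugs of their classes. A single deviating library is argued against, since 8 of 8 libraries scored above every alone library with the same autophagy inhibitor. Library depth is argued against, since at least 91.6% of the score was left after thinning every library to the smallest total. A lower ERK output score is argued against with hydroxychloroquine: 5 other drugs scored no higher for ERK output than ulixertinib (−1.86), and the highest ATF4 target score among them was 0.31 (RAF709), against 1.23 and 1.02. With the Vps34 inhibitor it stays open. There 4 other drugs scored no higher for ERK output than trametinib (−1.87), and SCH772984 among them had an ATF4 target score of 0.44 ± 0.14, against 0.75 ± 0.08 and 0.68 ± 0.12, a gap of less than 2 SD to ulixertinib. The remaining drugs among them lay lower, RAF709 at 0.35 ± 0.16, refametinib at 0.17 ± 0.08 and cobimetinib at 0.15 ± 0.01. A response of these cells to trametinib and ulixertinib that does not run through ERK output, or a difference in dose, stays open as an untested hypothesis.

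Genes with over 25% of their summed CPM in 1 library of a line numbered 205 in AsPC-1, spread over 62 of 68 libraries, and 203 in PANC-1, over 61. A response to the treatment is argued against as the cause of most of them, since the next highest library had the same treatment in 6 genes in AsPC-1 (5.21 expected, p = 0.422 by permutation) and in 7 in PANC-1 (5.60 expected, p = 0.325). A few poor libraries are argued against, since the 5 libraries with most of these genes held 21.0% and 22.2%. Errors in amplification or barcode assignment were not tested and stay open.

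The mitochondrial 12S ribosomal RNA took a larger share of counts with hydroxychloroquine in AsPC-1. Plate is argued against, since the smaller of the within-plate differences was 1.25 percentage points. More mitochondrial RNA of every kind is argued against, since the log2 ratio of hydroxychloroquine to Vps34 inhibitor was −0.19 for mitochondrial messenger RNA and 2.07 for 12S RNA. Counts of the neighbouring 16S RNA are argued against as the whole of it, since its log2 ratio was 0.34. An effect of either autophagy inhibitor on the processing, stability or capture of this RNA stays open as an untested hypothesis, since no untreated cells were measured to tell which of them changed it.

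Whether chance can give such counts was examined with other splits of the same libraries, 60 per comparison with the real split, 33 for binimetinib against selumetinib and 30 for both lines. These used simpler edgeR fits without drug groups, so the real counts differ from those reported. The results were not adjusted over the 43 comparisons. Chance can be excluded for the difference between autophagy inhibitors, with 734 genes in AsPC-1 against at most 7 in another split, and 119 in PANC-1 against 9. It can be excluded for the classes against alone in AsPC-1, where MEK gave 3614 against 482, ERK 3652 against 2 and RAF 424 against 8. In PANC-1 it can be excluded for MEK (2171 against 8) and ERK inhibitors (1334 against 1). RAF inhibitors in PANC-1 gave 7 against 6, too close to exclude chance. MEK and ERK inhibitors within each autophagy inhibitor gave 360 genes or more in both lines, where the highest other split was 626 against the real 1992 for ERK with hydroxychloroquine in AsPC-1, and chance can be excluded for all 8. The same holds for the 6 contrasts of class against class except MEK minus ERK in AsPC-1, with 9 against 5. It holds for the 6 tests among drugs of a class except ERK inhibitors in AsPC-1, with 10 against 6. Both exceptions are too close to exclude chance. For the classes, the splits moved single libraries and so broke up the libraries of each drug. What is excluded for them is a random division of libraries. Whether another sorting of the same drugs into classes would call as many genes was not tested. Binimetinib minus selumetinib in AsPC-1 gave 41 against 10, and no other of its 33 splits gave as many. So few splits, without adjustment over the 43 comparisons, do not by themselves exclude chance. Differences between the lines gave 1444 against 27 with MEK and 1623 against 4 with ERK inhibitors. There the splits cannot decide, since they move the kinase inhibitor labels within each line. They thereby remove the class effect itself and add it to the spread, whether or not the lines differ.

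Chance cannot be excluded for 3 further comparisons. RAF effects differed between the lines for 4 genes in this fit, and 9 of 30 splits gave as many, with at most 10 in another. Binimetinib minus selumetinib in PANC-1 gave 3, and 14 of 33 splits gave as many, with at most 9. The interaction of MEK inhibitors with the autophagy inhibitor in AsPC-1 gave 4, and 6 of 60 splits gave as many. The highest other split gave 63, and the reason was not looked into. For ERK inhibitors in AsPC-1 the interaction gave 7, and 2 of 60 splits gave as many, at most 10. These splits also move the kinase inhibitor labels and so remove the class effect. They therefore cannot exclude chance for this interaction.

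For 8 other comparisons the splits cannot tell, for a different reason. The simpler edgeR fit gave 0 genes in them, so all 60 splits gave as many by construction. RAF inhibitors within each autophagy inhibitor are 4 of these, with at most 6 in another split; with drug groups 392 and 484 genes passed in AsPC-1 and 52 and 32 in PANC-1. The others are the interaction with the autophagy inhibitor for RAF inhibitors in AsPC-1, with up to 18 in another split, and for each class in PANC-1, with up to 34. There the fit with drug groups gave 0 genes with edgeR, 725 at an unadjusted p under 0.05 in AsPC-1 and 778, 769 and 688 in PANC-1, and DESeq2 gave 5 in AsPC-1 and 4 for ERK inhibitors in PANC-1.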

How the results depend on the processing

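The alternatives were chosen before the data were examined, except 3 chosen after seeing the data: leaving out genes with over 25% of their summed CPM in 1 library, leaving out alone libraries from the class comparisons, and other settings for genes shared by the lines. No library had a total below 25% of the median of its line, so leaving out such libraries, also chosen before, was not run. Of 717 counts of genes under an alternative, 532 lay within 1.5 times the reported count. Log2 fold changes of named genes were tallied only under DESeq2, other size factors, other filters and no plate term. Fits within a plate, with drugs as replicates or with libraries left out are not in this tally. Leaving out 1 library turned some, such as IFI6 and SLC26A4 between the autophagy inhibitors. In the tally, direction and call were kept in 3035 of 3098 cases, while 61 lost the call, 2 gained it and none turned. Of these losses, 28 came without the filter on low counts and 31 without the plate term. Relative log expression size factors moved none of 99 counts by over 1.5 times, and a stricter filter none of 40. Tests of lists kept their call in 427 of 468 cases; 31 gained it, 28 of them with fry, and 10 lost it, 9 of them with an estimated correlation. ERK output scores moved by more than the SD between their 2 libraries in 76 of 168 cases, through the prior count or the gene left out. Depth limits what genes with few counts can show: the filter left 12761 and 12627 of 25435 genes in AsPC-1 and PANC-1. Where no cause is named below, the cause was not tested.

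DESeq2 called more genes in small contrasts. For the interaction with the autophagy inhibitor in AsPC-1 it gave 40 with MEK inhibitors (26 higher, 14 lower) in place of 12 (6 and 6), 113 with ERK inhibitors (58 and 55) in place of 40 (16 and 24), and 5 with RAF inhibitors in place of 0 with edgeR (725 at an unadjusted p under 0.05). In PANC-1 it gave 4 for that interaction with ERK inhibitors in place of 0 with edgeR (769 at an unadjusted p under 0.05). MEK minus ERK in AsPC-1 came to 168 in place of 95, and binimetinib minus selumetinib to 139 in place of 58 in AsPC-1 and to 4 in place of 0 with edgeR in PANC-1 (662 at an unadjusted p under 0.05). RAF inhibitors in PANC-1 came to 156 (48 higher, 108 lower) in place of 68 (13 and 55), and to 54 in place of 32 with the Vps34 inhibitor. RAF genes shared by the lines came to 10 higher and 43 lower in place of 5 and 27.

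Without the plate term, used as a replicate block, the interaction in AsPC-1 was 7 with MEK and 23 with ERK inhibitors. Binimetinib minus selumetinib there was 19, and 83 genes in place of 128 differed among ERK inhibitors. RAF effects differed between the lines for 153 genes in place of 235, and shared RAF genes were 3 higher and 15 lower. Beyond these and 2 single-drug counts, no count moved by over 1.5 times in this way. With drugs as replicates, which adds their differences to the spread, MEK minus ERK was 32 in AsPC-1 and 134 in PANC-1 (285 reported), and RAF in PANC-1 was 17. For RAF with the Vps34 inhibitor in PANC-1, 19 genes passed with no filter on low counts and 21 without genes with over 25% of their summed CPM in 1 library. With fry, 16 lists in place of 9 passed for MEK and 18 in place of 11 for ERK inhibitors in PANC-1.

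Fewer libraries gave fewer genes in most counts. Fits within a plate also treated drugs as replicates, so they changed the model as well as the libraries. Within plates A and B, the autophagy inhibitors differed in 91 and 21 genes in AsPC-1 (757 on both plates) and in 6 and 3 in PANC-1 (314). MEK inhibitors gave 2252 and 1542 in AsPC-1 (3692) and 664 and 868 in PANC-1 (2332). ERK inhibitors gave 472 and 497 in PANC-1 (1784) and 1789 on plate B in AsPC-1 (3971). RAF inhibitors gave 124 and 13 in AsPC-1 (1105) and 0 and 1 with edgeR in PANC-1 (940 and 764 at an unadjusted p under 0.05; 156 with DESeq2 on both plates). From the 12 alone libraries, the autophagy inhibitors differed in 140 genes in PANC-1; leaving out 1 alone library gave 205 (Vps34 inhibitor replicate 3) to 301.

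Leaving out replicate 1 or 2 of every combination, or 1 drug of the class, gave these ranges, in which a lone library is assumed to vary like the other groups. For MEK inhibitors they ran from 2329 to 3908 (without selumetinib) in AsPC-1 and from 1026 to 2380 (without selumetinib) in PANC-1, for ERK inhibitors from 662 to 1889 (without ravoxertinib) in PANC-1. For RAF inhibitors they ran from 422 to 1423 (without PLX8394) in AsPC-1 and from 5 (without RAF709) to 198 (without sorafenib) in PANC-1. With hydroxychloroquine, AsPC-1 gave 1458 to 1608 for MEK (2274 reported) and 155 to 200 for RAF (392). PANC-1 gave 500 to 510 for MEK (1272), 287 to 363 for ERK (896) and 10 to 17 for RAF (52). With the Vps34 inhibitor, AsPC-1 gave 1385 to 1574 for MEK (2298), 1991 to 2270 for ERK (2988) and 165 to 223 for RAF (484). PANC-1 gave 500 to 613 for MEK (1261), 286 to 402 for ERK (892) and, with edgeR, 0 to 3 for RAF (32; 1134 and 819 at an unadjusted p under 0.05, 54 with DESeq2 and all libraries). Binimetinib minus selumetinib gave 28 to 30 in AsPC-1 and 9 to 11 in PANC-1. The median over 28 single-drug comparisons was 409 to 470 in AsPC-1 (944) and 69 to 82.5 in PANC-1 (287).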

Other observations

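The gene lists and tests of this part were fixed before the data were examined, except the fits without a single library, which were chosen after the result was seen. Receptor tyrosine kinases and their adaptive partners moved both ways with kinase inhibitors. In AsPC-1, MEK inhibitors gave 5 higher and 5 lower of 18 (6 and 6 over the list alone, adjusted p = 0.774); the median was 0.09 and the mean 0.15, while the direction of the test was down. ERK inhibitors gave 5 higher and 7 lower in both counts (adjusted p = 0.332). FGFR1 changed by −1.12 ± 0.11 with MEK and −1.38 ± 0.11 with ERK inhibitors, EGFR by −1.02 ± 0.09 and −1.16 ± 0.10, and MET by −0.84 ± 0.10 with MEK inhibitors. ERBB3, chosen after its values were seen, rose by 1.39 ± 0.17 and 0.96 ± 0.17. In PANC-1, 3 were higher and 2 lower with MEK inhibitors (5 and 2 over the list alone, adjusted p = 0.163), with the PI3K subunit PIK3R3 at 0.72 ± 0.08, the ERBB3 ligand NRG1 at −1.31 ± 0.17 and MET at −0.58 ± 0.11.

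Autophagy genes also went both ways. With MEK inhibitors in AsPC-1, 11 of 48 were higher and 6 lower (12 and 8 over the list alone, adjusted p = 0.481). The conjugation factors ATG12 (−0.72 ± 0.06) and ATG16L1 (−1.35 ± 0.11) fell, and the cargo receptor SQSTM1 rose (0.53 ± 0.07). With ERK inhibitors 11 were higher and 6 lower in both counts (adjusted p = 0.249), SQSTM1 at 0.79 ± 0.07. In PANC-1, MEK inhibitors gave 7 higher and 3 lower in both counts (adjusted p = 0.163), the LC3 relative GABARAP at 0.49 ± 0.06 and ATG7 at −0.80 ± 0.12. ERK inhibitors gave 6 higher and 4 lower (7 and 4 over the list alone, adjusted p = 0.0851; adjusted p = 0.0498 with an estimated correlation). Between the autophagy inhibitors, SQSTM1 was higher with the Vps34 inhibitor in PANC-1 (0.40 ± 0.10; list adjusted p = 0.0505, and adjusted p = 0.027 with an estimated correlation) and MAP1LC3B lower in AsPC-1 (−0.54 ± 0.17, list adjusted p = 0.247).

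Glycolysis and hypoxia genes were split as well. With MEK inhibitors in AsPC-1, 4 of 33 were higher and 10 lower in both counts (adjusted p = 0.364), carbonic anhydrase 9 (CA9) at 1.47 ± 0.12, the phosphofructokinase PFKP at −0.76 ± 0.06 and pyruvate kinase (PKM) at −0.72 ± 0.06. With ERK inhibitors 3 were higher and 7 lower in both counts (adjusted p = 0.441); the median was 0.02, while the mean was −0.07 and the test pointed down. In PANC-1, MEK inhibitors gave 2 higher and 7 lower (2 and 8 over the list alone, adjusted p = 0.13), PFKP at −0.46 ± 0.07. Of 22 p53 targets in AsPC-1, 2 were higher and 4 lower with MEK inhibitors in both counts (adjusted p = 0.588). The cell cycle inhibitor CDKN1A fell by −1.07 ± 0.11, and in PANC-1 by −0.65 ± 0.10 with ERK inhibitors (3 higher and 2 lower of 20 targets in both counts, adjusted p = 0.344). Protein folding genes gave 5 of 26 higher with ERK inhibitors in AsPC-1 (3 over the list alone, adjusted p = 0.0941). Epithelial genes in PANC-1 gave 5 higher and 3 lower of 15 with MEK inhibitors (8 and 3 over the list alone, adjusted p = 0.317).

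Markers of other cell types were few. Fibroblast markers were higher with ERK inhibitors, 2 of 4 in AsPC-1 (adjusted p = 0.0255, LUM at 1.43 ± 0.11) and 2 of 3 in PANC-1 (adjusted p = 0.00858), in both counts, and both calls held with an estimated correlation. The call with RAF inhibitors in AsPC-1 (LUM alone higher in both counts, adjusted p = 0.0377) was lost, adjusted p = 0.0652 with an estimated correlation. Immune markers gave adjusted p values from 0.469 to 1 in AsPC-1, with 5 measured. In PANC-1, 2 were measured and not tested as a list, of which CD68 changed by −1.47 ± 0.46 with MEK inhibitors at 3.87 ± 2.04 CPM alone. The endothelial marker ESAM, 1 measured gene and so not tested as a list, fell in PANC-1 from 22.1 ± 5.07 to 8.40 ± 2.05 CPM with MEK inhibitors and by −1.62 ± 0.14 with ERK inhibitors.

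Single libraries also decided values in class comparisons. SLC4A1 in AsPC-1 lost its call without hydroxychloroquine-alone replicate 6, going from −3.41 to −1.31 with MEK, from −3.91 to −1.83 with ERK and from −3.19 to −1.11 with RAF inhibitors. CDH6 in PANC-1 kept its call with ERK inhibitors without hydroxychloroquine-alone replicate 3 (−3.72 to −2.83 ± 0.93, adjusted p = 0.0351). The share of counts from mitochondrial ribosomal RNA was higher with MEK inhibitors in AsPC-1 (5.14% ± 1.45, n = 20, against 4.02% ± 1.29, n = 12; permutation, adjusted p = 5.6e-04) and in PANC-1 (3.64% ± 0.91 against 2.70% ± 0.42, adjusted p = 0.02). In AsPC-1 it was higher with ERK (5.06% ± 1.18, n = 16, adjusted p = 5.6e-04) and RAF inhibitors too (4.75% ± 1.47, n = 20, adjusted p = 0.0347). In PANC-1 it did not pass with ERK (3.25% ± 0.74, adjusted p = 0.0803) or RAF inhibitors (3.65% ± 1.87, adjusted p = 0.111), where a library with hydroxychloroquine held 11.3%. The 12S RNA alone did pass there, at 0.620% ± 0.134 with ERK and 0.604% ± 0.127 with RAF inhibitors against 0.514% ± 0.0925 (adjusted p = 0.02 for each). In AsPC-1 it did not (adjusted p = 0.171 and 0.189).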
